A study of Mus musculus with 2 samples.

How the data were processed

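MicroRNA libraries were made from total RNA of heart tissue of 2 male B6CASTF1/J mice aged 25 days, with RNA below 30 nucleotides selected, per the labels. The age and source labels give 25 days, while the sample descriptions give 25 with months as the unit; days were used. The labels number the libraries as biological replicates 1 and 2, and the animals carry separate numbers, but both carry the same donor identifier. The libraries were treated as separate animals of 1 group; if they were not, the spread between them is technical. The deposited values are whole-number read counts per miRNA gene, and the authors' text accompanying the files names the build mm10 and the annotation GENCODE M21. The build is that of C57BL/6J, so reads of CAST alleles were counted against the other parent's sequence in both libraries. The aligner and the counting program are not given in the sources used here. Each file has 3 count columns, unstranded and 1 for each strand, and 4 further entries with reads that were unmapped, placed at several loci, outside miRNA genes, or ambiguous. Reads placed at several loci were tallied apart from the genes, per the row names of the deposited files, so genes with identical copies may be listed below their true level. Signal tracks and alignments that the accompanying text names were not analysed here.

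The column for the strand of the gene was used, since the opposite-strand column held 125 and 130 counts, 0.00254% and 0.00249% of the assigned counts, outside overlapping genes. Without strand, reads of the 64 miRNA genes that overlap another on the opposite strand are ambiguous, 1342888 reads in replicate 1 and 1438359 in replicate 2. Of the reads, 37.3% and 36.4% were assigned to a gene in replicates 1 and 2, 41.6% and 37.4% were placed at several loci, 15.0% and 20.2% were unmapped, and 6.03% and 6.00% lay outside miRNA genes. These 4 entries were left out of the totals and tests.

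All 2202 gene identifiers were matched to GENCODE M21, which gave symbols, coordinates in mm10 and host genes, and hairpin sequences came from its transcripts. Host genes are those on the same strand that contain the miRNA gene. A gene was called sharing when its hairpin holds a run of 20 bases, on either strand, of a miRNA gene at another locus; no genome sequence was searched, so copies outside annotated miRNA genes are not counted.

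Levels are assigned counts scaled to a library total of 1000000 (CPM), and log2 values use a pseudocount of 0.5 counts. A gene was detected with at least 10 counts in both libraries. Each gene was compared between the libraries by an exact conditional binomial test, two-sided, against the libraries' shares of the total, with Benjamini-Hochberg adjustment over detected genes at 0.05. The common biological coefficient of variation came from edgeR with an intercept only, because 1 group leaves no contrast for its quasi-likelihood test. List medians were placed among 10000 random lists of the same size, drawn from all listed genes, from detected genes, or matched on level for log2 ratios. Levels of neighbours and of sharing genes were tested with 100000 permutations across genes. Intervals of shares and ratios are exact (Clopper-Pearson) at 95%, and those of the correlation and the SD are bootstrap intervals over genes. Reads carry no molecular identifiers that the sources mention, so intervals cover counting error only.

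Before the data were examined, 16 gene lists with 173 entries were written, of which 4 listed names were matched through synonyms. Genes named in the text are the 20 with the highest mean CPM, the 5 with the largest absolute log2 ratio among those with a mean of at least 100 counts, up to 4 members of each list by mean CPM, members at 0 counts in the heart, endothelial, fibroblast and blood lists, and Mir208a and Mir208b. Others, such as the low Mir1a and Mir133a genes, Mir20a, Mir25, the Mir124a genes and members of the clusters, were named after their values were seen. Alternatives set before the data were examined changed the strand column, the count minimum, the scaling (TMM, DESeq2 size factors), the filter, the background of lists, the distance of neighbours, the length of the shared run, and left out each library in turn; others were chosen after seeing the data.

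The tests were tried on simulated data. Counts of 362 genes were simulated with counting error only, without the further spread between the real libraries. Of genes changed by 2-fold, 91.0% were called, and 3.39% of calls were unchanged genes. These rates therefore do not give the share of false calls between the 2 hearts. From a simulated coefficient of variation of 0.4, edgeR returned 0.416. Of 100 sets of shuffled levels, 4% gave a neighbour p below 0.05, and 6.67% of 60 unchanged sets gave a p below 0.05 in the permutation test of medians. Of 100 random lists of detected genes, 12% lay under the 5th or over the 95th percentile by level, and 8% by log2 ratio against matched lists, so a list beyond these limits can arise by chance. The random lists were drawn gene by gene, so the 8% does not cover lists of neighbouring genes. No adjustment was made over the 14 lists. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.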

Results

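MicroRNAs, the short regulatory RNAs that are cut from hairpin transcripts, were sequenced from the hearts of 2 male mice aged 25 days. The mice were B6CASTF1/J animals, the first-generation cross of the laboratory strain C57BL/6J with the wild-derived strain CAST. Both libraries form 1 group with 1 library per animal, and the labels define no contrast, so levels are given as mean ± SD with n = 2, and the only comparison between libraries is between the 2 hearts. The labels number the animals separately but give both the same donor identifier. Replicate 1 held 13210462 reads, of which 4930853 were assigned to a miRNA gene on its own strand, and replicate 2 held 14363882 reads, of which 5229819 were assigned. Levels are assigned counts scaled to a library total of 1000000 (CPM), and 1 count corresponds to 0.203 CPM in replicate 1 and 0.191 CPM in replicate 2. A gene with 0 counts can have a level of up to 0.608 CPM in replicate 1 and 0.574 CPM in replicate 2, and these limits, like all intervals below, cover counting error only.

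**Figure D1:**
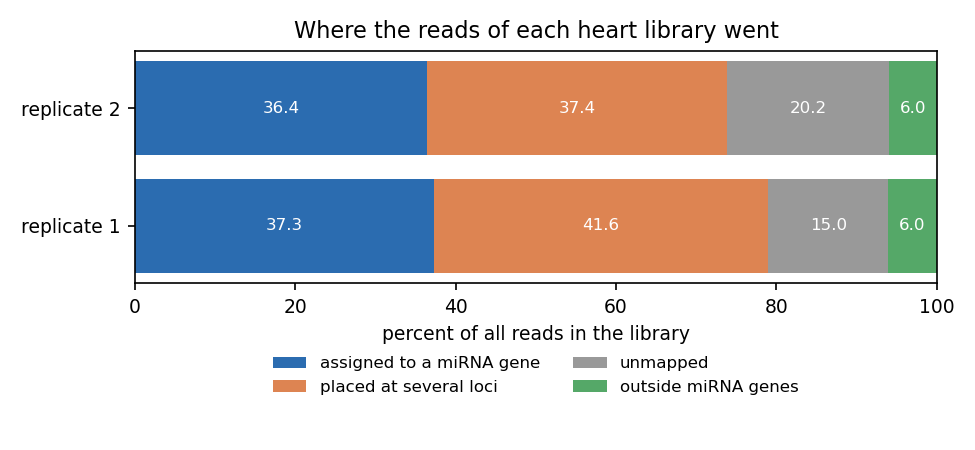
Horizontal bars show the percent of all reads of each heart library (x axis) that were assigned to a miRNA gene, placed at several loci, unmapped, or outside miRNA genes, with 1 bar per replicate. In replicate 1, 37.3% of reads were assigned and 41.6% were placed at several loci, and in replicate 2 these shares were 36.4% and 37.4%.

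Among reads assigned to 1 gene, Mir378a was the most abundant miRNA gene of the heart, at 172355 ± 4608 CPM, or 17.2 ± 0.461% of assigned counts (n = 2). It lies on chromosome 18 from 61397835 to 61397900 on the minus strand of mm10, within an intron of Ppargc1b, a coactivator of mitochondrial energy metabolism. The let-7 family, known for its rise during differentiation, followed with Mirlet7i at 93711 ± 7856 CPM, Mirlet7g at 65188 ± 1327 CPM, Mirlet7b at 57678 ± 5280 CPM and Mirlet7d at 47288 ± 4775 CPM. Mir126a, an endothelial miRNA within Egfl7 on chromosome 2 (26591357 to 26591429), was at 62907 ± 9214 CPM. Mir139, in an intron of the phosphodiesterase gene Pde2a on chromosome 7 (101475376 to 101475443), was at 40475 ± 6318 CPM, and the smooth muscle miRNA Mir143 was at 31702 ± 4152 CPM. The 10 most abundant genes held 66.8 ± 0.797% of assigned counts, and 50% of the counts came from 7 genes in replicate 1 and 6 in replicate 2. In replicate 1 these 10 genes held 67.4% (exact Clopper-Pearson 95% interval 67.4 to 67.4%) and in replicate 2 66.3% (66.2 to 66.3%). Counted against all reads, the 10 genes held 24.6%, and the reads placed at several loci, 1.11 and 1.03 for each assigned read, are in no gene's count, so this ranking leaves them out.

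Of the 2202 listed miRNA genes, 356 (16.2%) had at least 10 counts in both hearts and are called detected below, and 1448 had 0 counts in both. A minimum of 1 count gave 594 genes and a minimum of 100 counts gave 222. Mir378a, Mir23a and Mir23b, which are 3 of the 20 most abundant genes, share 20 bases with a miRNA gene at another locus, so their counts are uncertain where reads could be placed at more than 1 of the loci. Mir378a, Mir191 and Mir451a overlap a miRNA gene on the other strand, and the unstranded counts list all 3 at 0.

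**Figure D2:**
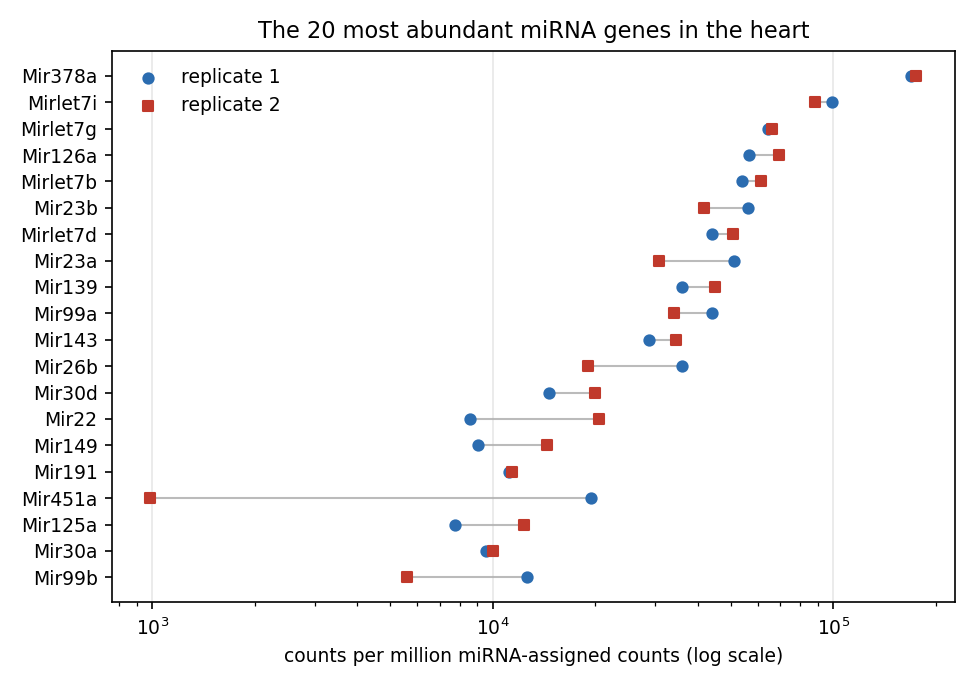
Points give the level of the 20 most abundant miRNA genes in replicate 1 (circles) and replicate 2 (squares) in CPM on a log axis, with a line joining the 2 hearts. Mir378a leads at 172355 CPM on average, and Mir451a shows the widest gap.

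Mir499, Mir208a and Mir208b, known from heart muscle, lie in introns of myosin heavy chain genes. Mir499, in an intron of Myh7b on chromosome 2 (155622880 to 155622958), was at 2846 ± 124 CPM. Mir208a, in an intron of Myh6, the alpha-myosin gene of the adult mouse heart, was at 2462 ± 1556 CPM (chromosome 14, 54949060 to 54949142, minus strand), and Mir208b, in an intron of Myh7, the beta-myosin gene, was at 191 ± 0.804 CPM (chromosome 14, 54975700 to 54975776, minus strand). Mir208a counts exceeded Mir208b counts by 7.13 times in replicate 1 (exact 95% interval 6.66 to 7.65) and by 18.6 times in replicate 2 (17.4 to 19.8). The odds of Mir208a over Mir208b were 2.60 times higher in replicate 2 (Fisher's exact test between the 2 libraries, two-sided p = 9.58e-87), with Mir208a higher there and Mir208b within counting error. That p-value covers counting error only. The log2 ratio of Mir208a between the hearts was 1.39, against an SD of 0.86 across detected genes. Ratios between genes also carry the ligation bias of small-RNA libraries.

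The muscle genes Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2 and Mir133b, which are known as leading miRNAs of heart muscle, had few counts. Mir1a-2 had 203 and 180 counts in replicates 1 and 2, Mir1a-1 had 14 and 12, Mir133a-1 had 3 and 30, Mir133a-2 had 6 and 7, and Mir133b had 7 and 10. These genes and Mir1b share 20 bases with a miRNA gene at another locus, and the levels of these 6 members lay between 0.979 and 37.8 CPM, against 6.22 to 2846 CPM for the 6 members that do not. The heart and striated muscle list, fixed before the data were examined, had 8 of 12 members detected and a median of 3.94 log2 CPM. The list held 0.655 ± 0.176% of counts, from which reads of its 6 sharing members placed at several loci are missing. That median lay at the 99.99th percentile of 10000 random lists of the same size from all listed miRNA genes, most of which are at 0, but the brain list (99.93) and the epithelial list (99.94) lay nearly as high, so the percentile does not set the heart genes apart. Among detected genes only, the 8 detected members lay at the 68.0th percentile, inside the range of random lists. The detected members of the brain (44.9), epithelial (19.3), liver (18.4) and pancreas and endocrine (14.7) lists lay lower on that background.

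Markers of the other cell types of the heart were also measured. The shares of lists leave out reads placed at several loci, and sharing genes make up 6 of 12 heart list members but 0 of 6 endothelial ones. Shares of lists with different numbers of sharing genes therefore do not rank them by true level. The endothelial list, led by Mir126a, held 6.67 ± 0.957% of counts, with Mir221 at 1852 ± 730 CPM and Mir10a at 1255 ± 508 CPM. The smooth muscle and fibroblast list held 3.97 ± 0.886%, with Mir21a at 3441 ± 2688 CPM and Mir214 at 3020 ± 1630 CPM. The leukocyte list held 0.726 ± 0.120%, led by Mir155 at 2759 ± 11 CPM and Mir150 at 1692 ± 390 CPM. The let-7 family held 28.3 ± 0.419%, the miR-30 family 3.38 ± 0.425%, the miR-29 family 0.301 ± 0.0497%, the miR-17/92 and paralogous clusters 1.54 ± 0.422% and the imprinted Dlk1-Dio3 cluster 0.703 ± 0.0331%. Lists named for other tissues held small shares: brain 0.0577 ± 0.0302%, epithelial 0.0439 ± 0.00259%, liver 0.00708 ± 0.000638%, pancreas and endocrine 0.00349 ± 0.00126%, early embryo 0.000839 ± 0.000132% and testis X-linked 0.000254 ± 0.000101%. By their medians most of these lists still lay above most random lists from all listed genes, at percentiles 99.93 (brain), 99.94 (epithelial), 98.82 (liver), 97.72 (pancreas and endocrine) and 91.81 (early embryo), while the testis X-linked list was at 40.375. In the early embryo list the percentile was 45.91 in replicate 1 and 96.325 in replicate 2. By their means single members were above the heart gene Mir208b (191 CPM): Mir200c of the epithelial list at 272 ± 64.3 CPM and Mir128-1 of the brain list at 240 ± 115 CPM. Mir128-1 was above it in replicate 1 only, at 322 CPM, and in replicate 2 lay at 159 CPM against 192 CPM for Mir208b. Mir122, abundant in liver, was at 20.8 ± 6.71 CPM, Mir124a-1, Mir124a-2 and Mir124a-3, abundant in neurons, were at 0 counts in both hearts but share 20 bases with a gene at another locus, so reads placed at several loci are missing from these counts, and 1 of 11 early embryo and 0 of 12 testis X-linked genes were detected.

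**Figure D3:**
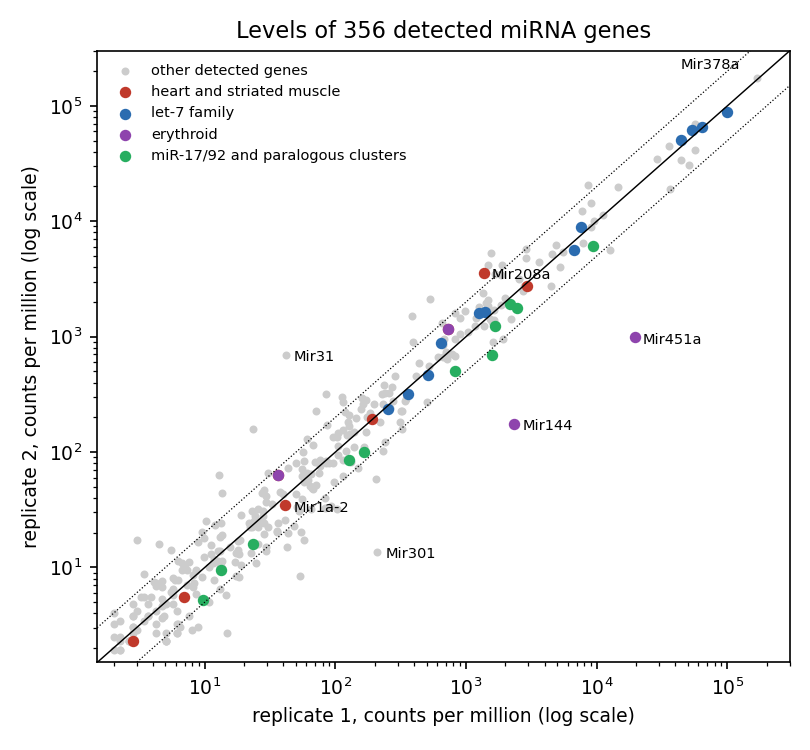
Each point is 1 of the 356 detected miRNA genes, with its level in replicate 1 on the x axis and in replicate 2 on the y axis, in CPM on log axes. The solid line marks equal levels and the dotted lines a difference of 2 times; Mir451a, Mir144, Mir301 and Mir31 lie far from the solid line.

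The largest ratio between the 2 hearts was that of Mir451a, and its neighbour Mir144 on chromosome 11 was among the 5 largest; both are known for their abundance in red blood cells. Mir451a (78073170 to 78073241) had 96105 counts in replicate 1 and 5159 in replicate 2, 19.8-fold higher in replicate 1 (exact 95% interval 19.2 to 20.3), and Mir144 (78073005 to 78073070) had 11445 and 914 counts, 13.3-fold higher (12.4 to 14.2). Mir301 was 15.3-fold higher in replicate 1 (12.0 to 19.7), while Mir31 was 16.8-fold higher in replicate 2 (14.6 to 19.4) and Mir26a-1 was 6.80-fold higher in replicate 2 (5.59 to 8.34). These 5 genes have the largest ratios among the 233 genes with a mean of at least 100 counts. Among the abundant named genes, Mir99b was 2.25-fold higher in replicate 1 (2.22 to 2.28), and Mir21a was 3.47-fold (3.38 to 3.56), Mir208a 2.62-fold (2.54 to 2.69), Mir22 2.40-fold (2.38 to 2.43) and Mir214 2.23-fold (2.18 to 2.29) higher in replicate 2. Outside the naming rule, Mir455 (4.06-fold), Mir34a (2.85-fold), Mir674 (2.09-fold) and Mir27b (2.02-fold) were also higher in replicate 2. Mir20a (2.25-fold) and Mir16-1 (2.03-fold) were higher in replicate 1. By contrast Mir208b, Mir192 and Mir155 did not differ beyond counting error with total-count scaling, and Mir155 was lower in replicate 2 with TMM scaling (log2 ratio -0.05, adjusted p = 0.00383, exact test).

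Across the 356 detected genes, log2 CPM in the hearts correlated with Spearman's rho 0.966 (0.953 to 0.974) and Pearson's r 0.973, a description across genes, which are not independent replicates. The SD of the log2 ratio was 0.86 (0.74 to 0.97), and edgeR's common biological coefficient of variation was 0.386. By the exact binomial test with Benjamini-Hochberg adjustment, 226 genes differed between the libraries beyond counting error, 117 higher and 109 lower in replicate 2, and 63 genes differed by more than 2-fold. This test compares the 2 libraries and not conditions, so with 1 library per animal a difference between the animals and one between the library preparations are measured together. Of the 20 most abundant genes, 13 were within 1.5-fold; 13 were higher and 7 lower in replicate 2, of which Mirlet7g and Mir191 turned lower, without a call, with TMM scaling.

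**Figure D4:**
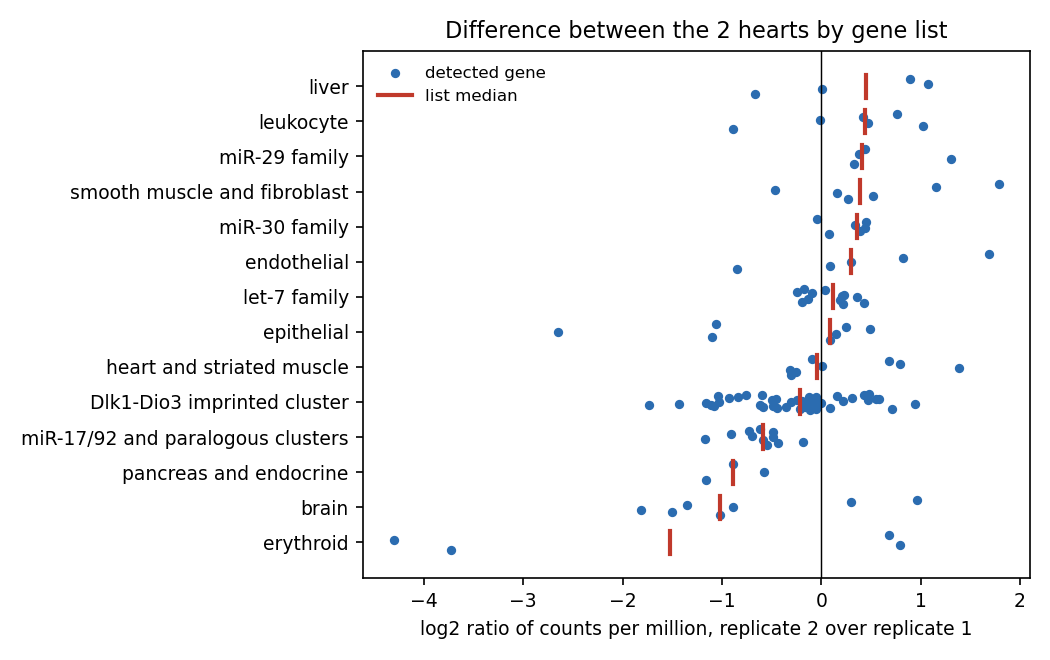
Each point is a detected gene of 1 of the 14 lists with at least 3 detected members, placed by its log2 ratio of CPM, replicate 2 over replicate 1 (x axis), with the list median as a bar. The lowest medians are those of the erythroid (-1.52), brain (-1.02), pancreas and endocrine (-0.89) and miR-17/92 (-0.59) lists, and the let-7 family has a median of 0.11, or 0.07 with TMM scaling.

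In the miR-17/92, brain, erythroid and Dlk1-Dio3 lists the median ratio lay below the 5th percentile of matched lists. The matched lists draw each gene on its own, whereas many members of these lists are neighbours or share bases with other genes. Since neighbouring genes had similar ratios, as given below, these percentiles can be too extreme. Of the 11 detected genes of the miR-17/92 and paralogous clusters, which promote proliferation, 10 were lower in replicate 2 and 1 was not called, with Mir93 at a log2 ratio of -0.62, Mir20a at -1.17 and Mir25 at -0.70. Their median of -0.59 lay at the 0.29th percentile of 10000 random lists matched on level. In the brain list 5 detected genes were lower in replicate 2, 1 was higher and 1 was not called, with a median of -1.02 at the 0.24th percentile, and Mir137 and Mir128-1 at -1.81 and -1.02; 12 of its 13 members share 20 bases with another gene. In the erythroid list Mir451a and Mir144 were lower in replicate 2 while Mir486 (log2 ratio 0.68) and Mir3107 (0.79), which overlap on opposite strands and are also in the heart list, were higher, so its median of -1.52, at percentile 0.62, lies between genes that moved apart, and the list held 2.26% of counts in replicate 1 and 0.240% in replicate 2. Of the 41 detected Dlk1-Dio3 genes, 22 were lower, 5 higher and 14 not called, with a median of -0.22 at the 3.86th percentile.

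The other lists did not lie beyond the 5th or 95th percentile of matched lists. All detected members of the let-7 family except Mirlet7f-1 were called, 7 higher and 4 lower in replicate 2, and with TMM scaling 6 higher and 5 lower, because Mirlet7g lost its call (log2 ratio -0.0035) and Mirlet7f-1 gained one as lower (log2 ratio -0.14). The miR-30 family had 5 genes higher and 1 lower, the miR-29 family 3 higher and 1 not called, and the smooth muscle and fibroblast list 4 higher, among them Mir21a, Mir214 and Mir145a, and 2 not called. The endothelial list had 4 higher, among them Mir126a, and 1 lower, Mir10a, and with TMM or DESeq2 scaling 3 higher because Mir10b lost its call. The leukocyte list had 4 higher, 1 lower and 1 not called, the heart and striated muscle list 3 higher, 1 lower and 4 not called, the epithelial list 2 higher, 3 lower and 2 not called, the liver list 2 higher, 1 lower and 1 not called, and the pancreas and endocrine list 1 lower and 2 not called. Besides these let-7 and endothelial genes, with TMM scaling Mir155 and Mir7-2 gained a call as lower in replicate 2 and Mir203 lost its call as higher. Adjusted over the list alone, the number of calls in each of the 14 lists was the same as over all genes.

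Genes that share 20 bases with a miRNA gene at another locus, such as Mir1a-1 and Mir133a-2, were detected less often than genes that do not. Of the 1087 sharing genes 78 (7.18%) were detected, and of the 1115 others 278 (24.9%), an odds ratio of 0.233 (Fisher's exact test across genes, two-sided p = 6.93e-31). Sharing genes are copies of one another and not independent, so the p-values across genes in this part overstate the evidence. The sharing genes still held 30.4% and 28.0% of assigned counts in replicates 1 and 2. Most of this lay in 3 genes, Mir378a (17.2% on average), Mir23b (4.9%) and Mir23a (4.1%). The difference of the medians was -1.16 log2 CPM (permutation p = 1e-05, the smallest the permutations can give), but the sharing median sits at the level of 0 counts and the difference was 0 in each library alone. Among detected genes the sharing genes were 0.36 log2 CPM higher, which was not distinguishable from 0 (permutation p = 0.502).

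Over the pairs tested, neighbouring miRNA genes, which are often cut from 1 transcript, had levels more alike than random pairs. The median absolute difference of log2 CPM was 2.76 over 103 pairs of adjacent detected genes within 10 kb on the same strand, against 3.45 in permutations (one-sided permutation p = 0.0429). With a limit of 1 kb the median was 3.01 and the test was not passed (permutation p = 0.198). Clusters of 33 and 11 detected genes on chromosome 12 supplied many of the 103 pairs. The test was not run without them, so it does not show that neighbours are alike in general. Within single clusters, Mir99b, Mirlet7e and Mir125a on chromosome 17 spanned 0.73 log2 CPM in replicate 1 and 1.14 in replicate 2. In the same replicates Mir23b, Mir27b and Mir24-1 on chromosome 13 spanned 9.71 and 8.51 log2 CPM. Both clusters were chosen after their values were seen. Sharing genes, such as Mir23b, Mirlet7c-2 and Mir29b-1, were kept in the pairs and clusters, and their reads placed at several loci are missing. A wide span can therefore come from the counting and does not show unequal output of 1 transcript.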

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

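The tests of red blood cell miRNAs, of the opposite strand, of sharing within the lists and of ratios between neighbours were chosen after the results were seen; those of GC content were set before. The design names no biological difference between the libraries, since there is 1 group, so beyond cell content and shared transcripts no biological explanation was tested.

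Signal appeared in data that the report's comparisons do not use. Reads placed at several loci numbered 5497619 in replicate 1 and 5375745 in replicate 2, or 1.11 and 1.03 for each assigned read. Reads outside miRNA genes numbered 795982 and 861768. Opposite-strand counts at genes without an overlapping miRNA gene numbered 125 and 130, of which Mir122 held 46 and 53 against 126 and 84 on its own strand.

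The first pattern is the high level of Mir451a and Mir144 in replicate 1. A shift of counts to the opposite strand is argued against: at the level of replicate 1, 107998 more counts would lie at these genes in replicate 2, and 0% of them were found on the opposite strand, which held 0 counts at both genes, as did Mir451b, the gene that overlaps Mir451a. An earlier test, which added the strands, was dropped because adding 0 counts moves nothing. The outcome of the test given here was therefore known when it was set. A linear effect of hairpin GC content is also argued against, since it was hardly correlated with the log2 ratio over the 356 detected genes (Spearman's rho 0.016). The fit on it moved the ratios little and left residuals of -4.30 for Mir451a and -3.73 for Mir144. The GC content of the mature sequences was not tested. A candidate explanation is a different amount of red blood cells in the hearts. A list of 13 other miRNA genes abundant in red cells was written after several of its members had been seen; its 11 detected genes, 6 lower and 5 higher in replicate 2, had a median of -0.48 at percentile 0.62 of matched lists, which on its own would favour the explanation, but after that value was seen the deciding value was changed to the 5 genes in none of the earlier lists, whose median was 0.23 at percentile 60.94. Among these 5, Mir16-1, Mir16-2, Mir107 and Mir103-2 share 20 bases with a gene at another locus. Their reads placed at several loci are missing, so the deciding value rests largely on incomplete counts. With Mir16-1 at -1.02 (9445 and 4941 counts), Mir107 at 1.99 (1896 and 7965 counts) and Mir486 at 0.68, the members of the list move apart, so red cells and other causes cannot be told apart here.

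The second pattern is the few counts of Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2. A candidate explanation is that their reads were placed at several loci and left out of the gene counts. Within 13 of the lists, the 50 genes that share 20 bases lay on average -3.81 log2 CPM from the 102 other members of their lists, about 14.0-fold (permutation p = 0.0002 with sharing labels permuted within lists). The Mir1a and Mir133a genes are among those 50. Without the heart list the difference was -3.43 log2 CPM over 44 and 96 genes in 12 lists (permutation p = 0.0011). The brain list supplied 12 of those 44, set against Mir137 alone, and its Mir124a genes may be at 0 counts for other reasons. Among all detected genes the sharing genes were 0.36 log2 CPM higher (permutation p = 0.502). Sharing genes are copies of one another, so these p-values overstate the evidence. The reads at several loci were not assigned to genes in the counts used here, so how many come from Mir1a or Mir133a stays open.

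The third pattern is that 226 of 356 detected genes differed between the hearts beyond counting error. A linear effect of hairpin GC content is argued against as the main cause, since a fit on it lowered the SD of the log2 ratios by 0.00155%. The GC content of the mature sequences that were read was not tested. Neighbouring genes had more similar ratios than random pairs, with a median absolute difference of 0.53 against 0.68 (one-sided permutation p = 0.0208). Without the Mir451a and Mir144 pair the median was 0.52 (permutation p = 0.0185). Part of the difference may therefore arise in shared transcripts. Many of these pairs lie in the chromosome 12 clusters with 33 and 11 detected genes. These were not left out, so the likeness may not hold for neighbours in general. Differences between the animals and between library preparations both stay open, since each animal has 1 library.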

How the results depend on the processing

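The alternatives for sharing genes among detected genes and within lists, with and without the heart list, for the top 10 share without overlapping genes, for the heart list without sharing members, for detected genes without sharing genes, and without Mir451a and Mir144 were chosen after seeing the data. No paired analysis was possible because there is 1 group.

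The detected genes numbered 594 with a minimum of 1 count and 222 with a minimum of 100, by the construction of the filter, and between 278 and 386 under the others. The share of the 10 most abundant genes was 67.8% with unstranded counts, 67.8% without genes overlapping on the opposite strand and 24.6% of all reads. In single libraries, with the 10 genes chosen anew in each, it was 66.7 to 67.4%, while the fixed 10 genes held 66.3% in replicate 2. Spearman's rho was 0.899 without a filter and 0.947 with a filter of 100 counts, and the SD of the log2 ratio was 1.42 without a filter, where low counts enter. The genes that differed numbered 180 to 242 over all alternatives, against 226, and under the scalings and filters 48.0 to 56.1% of them were higher in replicate 2. The common biological coefficient of variation was 0.380 to 0.430. The scalings moved the log2 ratios by -0.045 (TMM) and -0.021 (DESeq2 size factors) and leave neighbour and sharing tests as they are, so these were not run for them.

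The heart list lay at percentile 99.78 with unstranded counts and at 99.98 to 99.99 in single libraries. Among detected genes it lay at percentile 68.22, which differs from the 68.0 given above only by the random draws. Its median was 1.38 log2 CPM with unstranded counts, 6.58 over detected members and 8.72 over members that share no 20 bases. The Mir208a to Mir208b ratio was 7.13 to 18.6 in single libraries. Neighbours within 1 kb differed by 3.01 (permutation p = 0.198), with 63 pairs in place of 103, and by 2.40 to 2.62 under the other alternatives, all with permutation p below the threshold. The sharing difference was 0 in each library alone, where both medians sit at 0 counts, and 0.36 among detected genes; with 18 or 22 bases it was -1.16.

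With TMM scaling Mirlet7g went from a log2 ratio of 0.04 to -0.0035 (adjusted p = 0.423, exact test) and Mir191 from 0.03 to -0.012 (adjusted p = 0.208, exact test), by the shift of the scaling. Mir208b (0.0085) and Mir192 (0.0037), not called under any scaling, turned to -0.036 and -0.041 with TMM and to -0.013 and -0.017 with DESeq2 size factors. Of the 69 named genes tested, 61 kept direction and call with TMM and 65 with DESeq2 size factors. Of the 80 named genes, 64 have the same raw counts with and without strand, and where these are above 0 the unstranded level is higher only because the stranded total is 1.37 and 1.38 times the unstranded one in replicates 1 and 2. The other 16 have other raw counts, and 7 of these, among them Mir378a, Mir191, Mir451a, Mir486 and Mir30e, have counts with strand and are listed at 0 without it; Mir126a went from 278061 and 363065 counts to 13 and 17. Depth limits the low genes: a gene with 0 counts can have up to 0.608 CPM.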

Other observations

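The clusters and ratios in this part were chosen after their values were seen, and are given as values without a further test.

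The leading miRNAs of several transcripts were measured side by side. Mir143 and Mir145a, neighbours on chromosome 18 known from smooth muscle, held 3.32 ± 0.454% of counts (SD, n = 2) and both were higher in replicate 2. Mir23b, Mir27b and Mir24-1 held 5.35 ± 0.814%, and Mir23a, Mir27a and Mir24-2 held 4.22 ± 1.38%, most of it in the Mir23 genes. The cluster of Mir322, Mir351, Mir503, Mir542, Mir450-1, Mir450-2 and Mir450b on the X chromosome (53047997 to 53054349) held 0.694 ± 0.0406% with 7 of 7 genes detected, at 0.722% in replicate 1 and 0.665% in replicate 2. Its most abundant gene, Mir322, was lower in replicate 2 (25578 and 21045 counts), while the other 6 had higher levels there, of which Mir450b and Mir450-1 were within counting error. Mir221 and Mir222, also on the X chromosome, held 0.141% in replicate 1 and 0.259% in replicate 2.

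The counts of Mir126a and Mir143 kept nearly the same ratio in both hearts, 1.96 in replicate 1 and 2.00 in replicate 2, while Mir21a over Mir143 was 0.0535 and 0.154. Mir499 over Mir208b was 15.4 and 14.4, and Mir499 over Mir208a was 2.15 and 0.774.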
